A study of Mus musculus with 6 samples.

How the data were processed

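The deposited table held 1 processed intensity per probe set for each of 6 Affymetrix 3' expression arrays hybridised with biotin-labelled small intestine RNA. Per the submitters' processing notes, Partek and RMA were used, with no versions, parameters or roles given. The deposited intensities ran from 3.82 to 31146 and were therefore on a linear scale, although log2 values had been assumed when the tests were fixed; log2 was taken before any test, with no pseudocount. The quartiles of the 6 arrays were nearly equal, as after normalization between arrays, but the step that made them so is not given in the sources used here. No further normalization was applied. Each array held RNA pooled from 6 to 8 mice of 1 genotype killed on 1 day, per the labels, so the spread between single mice cannot be seen. For single genes, p-values over the 3 days measure only how far the genotype difference varied between the days. Those for its change with day measure only how far the 3 differences departed from a straight line.

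The table had 45101 probe sets, of which 64 were controls. In the platform annotation 34945 probe sets had 1 gene, 932 had several and 9160 were not listed, which leaves them unnamed here. Symbols of 34741 probe sets were updated through the gene ID to the names of assembly GRCm38.p6. The build behind the array is not stated, so no coordinates are given. Probe sets with several genes were left out. For each of 18193 genes the probe set with the highest mean log2 intensity was used, and genes were kept when that mean lay above the 40th percentile of all non-control probe sets (log2 5.28, an intensity of 38.9), which left 13042 genes. Arrays give no detection call in this table, so a dim probe set was judged by that threshold alone. For named genes with an array below it, differences were also computed with such intensities raised to the threshold, a step added after the values were seen.

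The genotype difference over the 3 days was tested with limma 3.58.1 in R 4.3.3, with day as a factor and genotype as the tested term (lmFit and eBayes, two-sided), over all 6 arrays. That fit has 2 residual degrees of freedom plus a prior of 3.03. Its change with day was tested as the product of genotype and centred day beside day as a factor and genotype, which leaves 1 residual degree of freedom plus a prior of 4.76. Both were adjusted by Benjamini-Hochberg at 0.05. SD is that of the difference over the 3 days and SE that of the moderated fit. For 43 gene lists written before the data were examined, 42 with at least 3 measured genes were tested in the same fits with camera at its preset correlation of 0.01, and again with an estimated correlation and with fry. Camera at the preset takes genes to be nearly independent, so its p-values rest largely on the spread between genes. Differences on a single day have no replicate and no test. They were described by the number of genes at 2-fold or more and by each list's median with its percentile among 10000 random lists matched on mean expression in 20 bins.

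Genes named in the text followed a rule fixed before the data were examined: 20 fixed genes, the 12 highest and lowest mean differences with the same sign on all days (those past the threshold first), the 8 highest and lowest differences on each day, the 8 highest and lowest slopes past the threshold, the 5 highest and lowest changes from day 2 to day 5 in L/L, and up to 4 members of each list with the largest value of the quantity given. Sex-linked genes, immunoglobulin and T cell receptor segments and unnamed gene models were passed over except in the lists for sex. A gene that several parts of the rule picked is named under each.

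Both fits were tested on simulated data, with 200 of 13042 genes changed. The test over the 3 days recovered 28.4% of genes changed by 0.5, 83.6% of those changed by 1 and 100% of those changed by 2 on the log2 scale, with 8 false among 149 calls, and made no call when no gene was changed. The slope test recovered 20.9%, 97% and 100% of genes changing by 0.25, 0.5 and 1 per day, with 16 false among 161 calls. Camera with the preset correlation recovered all 10 lists shifted by 0.3 over the 3 days and camera with an estimated correlation 0 of them. In a design of this size the latter thus has little power. The simulated noise was independent between genes, so the simulation cannot show how the preset does where genes of a list vary together. In the data the estimated correlation was 0.919 for oxidative phosphorylation, 0.896 for sterol synthesis, 0.41 for p53 targets and 0.0181 for interferon genes.

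Alternatives fixed beforehand were the mean of all probe sets of a gene, leaving out probe sets that can bind several transcripts, no filter and a filter at the 60th percentile, an offset of 32 before log2, centring on the median, cyclic loess, the trend and robust settings of eBayes, leaving out each day, no day term, a linear day term, a 1.5-fold minimum, and other codings of the change with day. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.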

Results

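Gene expression was measured in the mouse small intestine after tamoxifen-induced deletion of Fitm2 (FIT2), which encodes a protein of the endoplasmic reticulum needed for lipid droplet formation. Control mice were labelled L/L, a notation not spelled out in the labels that usually denotes loxP-flanked alleles. The deletion mice, called KO here as in the labels, carried the same alleles together with ROSA26-CreERT2, a Cre recombinase that tamoxifen activates. Tamoxifen was injected at 100 µg per g body weight on days 1, 2 and 3, and the whole small intestine was taken on day 2, 3 or 5. The labels do not say whether mice killed on day 2 or 3 had received the later doses. RNA was pooled before hybridisation, from 6 mice for L/L day 2, 7 for KO day 2, 6 for L/L day 3, 6 for KO day 3, 8 for L/L day 5 and 7 for KO day 5. Each pool gave 1 array, so no genotype had a replicate within a day. The number of arrays, 6 in all, limits the precision of every comparison. After removal of dim genes, 13042 genes were compared. The median intensity over all probe sets lay between 57.8 on L/L day 3 and 59.8 on KO day 5. Over the genes kept, the correlation of log2 intensity between arrays was highest for L/L day 2 and KO day 2, at 0.997, and lowest for L/L day 2 and KO day 5, at 0.978.

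The Fitm2 probe set was lower in KO on each day. Its intensity was 193 in L/L and 123 in KO on day 2, 223 and 127 on day 3, and 211 and 120 on day 5. The mean log2 difference over the 3 days was -0.76 ± 0.10 (SD over 3 days; SE 0.07), which did not pass the limma test after adjustment over all genes (adjusted p = 0.125). The deleted part of the gene and its position relative to the probe set are not given in the sources used here, so this value does not show how complete the deletion was. The related gene Fitm1 differed by -0.03 (adjusted p = 0.857), with intensities between 159 and 176 on the 6 arrays. Gt(ROSA)26Sor, the transcript of the locus that carries the Cre insertion, was also lower in KO on each day, by -1.11, -1.77 and -1.48 on the log2 scale, without passing the test (adjusted p = 0.125).

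Over all 3 days, the question was which transcripts separated KO from L/L regardless of day. Esr1, Glipr1 and Ifit1 rose in KO and no gene fell. Esr1, the estrogen receptor alpha gene, had intensities of 56.1, 56.1 and 39.8 in L/L and 367, 465 and 355 in KO on days 2, 3 and 5, a mean 7.85-fold difference (log2 2.97 ± 0.23 SD, adjusted p = 0.0113). A dimmer Esr1 probe set above the filter differed by only 0.10. Glipr1 was 2.99-fold higher (log2 1.58 ± 0.09 SD, adjusted p = 0.0148). Ifit1, an interferon-induced antiviral gene, was 2.25-fold higher (log2 1.17 ± 0.05 SD, adjusted p = 0.0285), with intensities of 1178, 1476 and 1704 in L/L and 2743, 3276 and 3739 in KO. These 3 were the genes past the threshold among 13042, and 1603 had an unadjusted p under 0.05 where 652 were expected by chance. Without day 2 limma called Esr1 alone (Glipr1 1.60, adjusted p = 0.0558; Ifit1 1.14, adjusted p = 0.0739), and without day 5 Esr1 and Glipr1 (Ifit1 1.19, adjusted p = 0.0504). Without day 3 it called 0 genes (Esr1 2.93, adjusted p = 0.599; Glipr1 1.61, adjusted p = 0.651; Ifit1 1.18, adjusted p = 0.753), with 606 at an unadjusted p under 0.05. With the mean of all probe sets of a gene Esr1 was 1.10 higher (adjusted p = 0.138) and Glipr1 0.97 (adjusted p = 0.0808), and Ifit1 alone passed. Ifit1 did not pass without the intensity filter (adjusted p = 0.0524) or without the day term (adjusted p = 0.438). The difference had 1 sign on all 3 days in 5159 genes (39.6%, against 25% by chance).

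Several larger mean differences varied too much between days to pass. Among genes with the same sign on each day, the highest of these were Psrc1 (log2 2.00, SE 0.37), Phlda3 (1.48, SE 0.29), Il1rn (1.48, SE 0.66), Ephx1 (1.43, SE 0.25) and Ccng1 (1.38, SE 0.21), with Egr1, Usp18, Ccp110 and Zmat3 between 1.20 and 1.31. The brightest probe set of each gene is the one given; another above the filter differed by 0.99 for Psrc1 and -0.28 for Svip, and others of C1qtnf12 by -1.02, -0.60 and -0.13. The lowest, apart from Gt(ROSA)26Sor, were Car4 (-2.07, SE 0.75), which encodes a carbonic anhydrase, Dmbt1 (-1.66, SE 0.72), a mucosal scavenger glycoprotein, Nox4 (-1.17, SE 0.30), Ugt2b5 (-1.14, SE 0.50) and Capn13 (-1.06, SE 0.25), followed by Dio1, Pbld1, Ugt2b36 (-0.98), Reg3a (-0.97), C1qtnf12 (-0.93) and Svip (-0.92). Adjusted p for these lay between 0.24 and 0.416. Nox4 and Pbld1 were below the filter threshold in KO on days 3 and 5; with those intensities raised to the threshold, a step chosen after the values were seen, their mean differences were -0.97 and -0.56. Il1rn was below it on 4 arrays, both of day 2 included, so its mean has no bound.

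**Figure D1:**
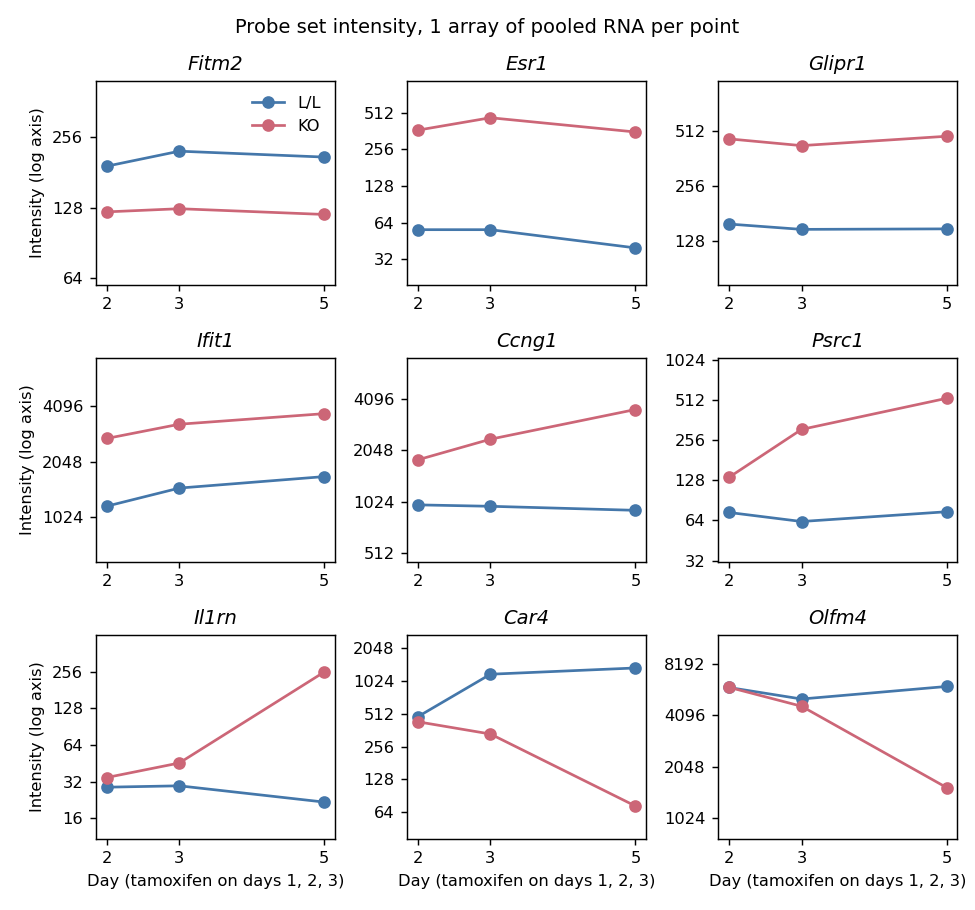
Probe set intensity (vertical, log axis) on days 2, 3 and 5 (horizontal) for 9 genes, with L/L in blue and KO in red and each point 1 array of pooled RNA. Esr1, Glipr1 and Ifit1 are apart on all 3 days, Ccng1 and Psrc1 separate progressively, and Il1rn, Car4 and Olfm4 are furthest apart on day 5, where KO stands at 255, 73 and 1545.

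Interferon response genes were higher in KO from day 2 onwards. Of 31 measured, 28 were higher on all 3 days and none lower on all 3, with a median log2 difference of 0.45 on day 2, 0.46 on day 3 and 0.64 on day 5. The largest mean differences were those of Usp18 (1.24), Ifit1 (1.17), Ifit3 (1.08) and Rsad2 (1.01). Of the list, 1 gene rose after adjustment over all genes and 25 rose when adjusted over the list alone. The list passed camera with its preset correlation (adjusted p = 9.81e-21). It did not pass with an estimated correlation (adjusted p = 0.516) or by fry (adjusted p = 0.0689). Between L/L arrays alone the same list moved by up to 0.25, from day 2 to day 3.

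Targets of p53, the transcription factor activated by DNA damage, were also higher in KO, increasingly so by day. The median difference was 0.19 on day 2, 0.44 on day 3 and 0.61 on day 5, and 24 of 28 genes were higher on all 3 days. Psrc1 led the list, followed by Phlda3, Ccng1 (cyclin G1; 0.88, 1.31 and 1.96 by day) and Zmat3 (0.57, 1.14 and 1.89). The cell cycle inhibitor Cdkn1a (p21) stood at 0.27, 0.39 and 0.82. None of the 28 passed over all genes and 20 passed when adjusted over the list alone, with 21 at an unadjusted p under 0.05 in limma. Camera gave adjusted p = 1.47e-12 with the preset correlation and adjusted p = 0.791 with an estimated correlation; fry gave adjusted p = 0.497.

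Of the secretory lineages, Paneth cell genes were higher in KO, with medians of 0.12, 0.39 and 0.74 over 9 genes measured of 22 written, none of which passed over all genes and 6 of which passed when adjusted over the list alone. Itln1 (0.83), Ang4 (0.62), Nupr1 (0.62) and Mmp7 (0.54) had the largest means, and Lyz1, the Paneth cell lysozyme, differed by 0.34. Nupr1 is also on the amino acid response list. Pla2g2a, of the Paneth cell list, was at least 2-fold lower on day 2. Enteroendocrine genes had medians of 0.01, 0.22 and 0.41 over 24 genes, with Gcg (0.56), Gip (0.47), Chgb (0.46) and Sst (0.43) in front. Goblet cell genes had medians of 0.03, 0.17 and 0.08, Muc2 a mean of 0.19 and Spink4 0.47. Camera's adjusted p for these 3 lists was 0.000225, 0.000253 and 0.0335 with the preset correlation, and adjusted p = 0.791 for each with an estimated correlation. No enteroendocrine or goblet cell gene passed when adjusted over its own list. The goblet call was lost without day 3 (median 0.05, adjusted p = 0.333), without the intensity filter (adjusted p = 0.0534) and with arrays centred on the median (adjusted p = 0.0547), and without day 2 its median was 0.15 (adjusted p = 0.0147). Without day 5 the Paneth cell and enteroendocrine medians dropped to 0.25 and 0.09, still past the threshold (adjusted p = 0.000162 and 0.00128). Tuft cell genes had a median of 0.00 over the 3 days (adjusted p = 0.994).

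Genes of several non-epithelial cell types were higher in KO as well. Endothelial genes had medians of 0.09, 0.25 and 0.41 and 15 of 17 were higher on all 3 days, led by Lyve1 (0.51), Robo4 (0.39), Plvap (0.37) and Esam (0.35). Myeloid genes had medians of 0.10, 0.26 and 0.70, led by Lyz2 (0.69), C1qa (0.63), C1qb (0.55) and Mrc1 (0.50). Fibroblast and matrix genes had medians of 0.02, 0.15 and 0.49, led by Pdgfra (0.53), Timp1 (0.52), Mmp2 (0.44) and Bgn (0.44). Camera's adjusted p was 3.1e-07, 1.44e-05 and 0.000159, and adjusted p = 0.791 for each with an estimated correlation. Adjusted over each list alone, 3 endothelial genes passed and no myeloid or fibroblast gene did. Without day 5 the endothelial, myeloid and fibroblast medians dropped to 0.18, 0.14 and 0.08, still past the threshold (adjusted p = 4.46e-07, 7.55e-05 and 0.00524), and without day 2 the fibroblast median was 0.33. The lists for T and NK cells (-0.05), B and plasma cells (-0.02), mast cells and eosinophils (0.03), smooth muscle (0.04), enteric neurons and glia (0.09), adipocytes (0.13), pancreatic acinar cells (0.16), erythroid cells (-0.05) and hepatocytes (0.10) did not pass, with median differences over the 3 days as given.

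Lipid handling is the process Fitm2 takes part in. Lipid absorption and chylomicron genes had medians of 0.02, 0.01 and 0.09 over 27 genes (adjusted p = 0.354). The triglyceride synthesis enzymes Dgat1, Dgat2 and Mogat2 had mean differences of -0.10, 0.18 and -0.09. A second bright Dgat2 probe set differed by 0.46, and by 1.00 on day 5. The values were 0.09 and 0.20 for Mttp and Apob, which assemble chylomicrons. Lipid droplet and lipolysis genes passed camera narrowly, with medians of 0.01, 0.08 and 0.21 over 20 genes (adjusted p = 0.0278, and adjusted p = 0.791 with an estimated correlation). The call was lost without day 5 (median 0.06, adjusted p = 0.221), and without day 2 the median was 0.17. Of the 20 genes, 1 passed when adjusted over the list alone. Their largest mean differences were those of Hsd17b13 (-0.79), G0s2 (0.44), Abhd5 (0.32) and Ces1d (0.32), while Plin2 (0.03), Plin3 (0.23) and Bscl2 (0.23) lay closer to 0. A dim second Hsd17b13 probe set differed by -0.05. Phospholipid synthesis (median 0.02), sphingolipid metabolism (-0.00) and fatty acid synthesis (-0.07) did not pass.

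Oxidative phosphorylation genes were lower in KO, by medians of -0.03, -0.12 and -0.39, with 18 of 25 lower on all 3 days and none higher on all 3. Cyc1 (-0.32), Ndufs1 (-0.32), Uqcrfs1 (-0.31) and Sdhd (-0.30) had the largest means. Sterol synthesis genes turned over time, with medians of 0.16, -0.15 and -0.39, and Stard4 (-0.33), Insig1 (-0.30), Dhcr7 (-0.27) and Tm7sf2 (-0.27) were lowest on average. Fatty acid oxidation genes had medians of 0.01, -0.05 and -0.35. The largest mean differences among them were those of Angptl4 (0.74), Acadm (-0.36), Decr1 (-0.34) and Ppargc1a (-0.31). Camera's adjusted p was 2.68e-07, 0.0117 and 0.049 for the 3 lists, and adjusted p = 0.791, 0.825 and 0.825 with an estimated correlation. No gene of the 3 lists passed when adjusted over its own list. Without day 5 the oxidative phosphorylation median was -0.07 (adjusted p = 0.00132), the sterol median 0.02 (adjusted p = 0.759) and the fatty acid oxidation median -0.02 (adjusted p = 0.914). The sterol median was -0.26 without day 2 and -0.08 without day 3 (adjusted p = 0.0513). The fatty acid oxidation call was also lost with the mean of all probe sets (adjusted p = 0.0929), the stricter filter (0.066), median centring (0.105) and cyclic loess (0.0606).

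Amino acid response genes, the targets of ATF4, were higher on each day, with medians of 0.19, 0.23 and 0.15 over 21 genes. Vldlr (0.89), Ddit4 (0.66), Nupr1 (0.62) and Psat1 (0.60) led. Other Vldlr probe sets above the filter differed by 0.52 and 0.08, and another of Nupr1 by 0.32. None passed over all genes, and 10 rose and 1 fell when adjusted over the list alone. Glucocorticoid response and fasting genes had medians of 0.20, 0.38 and 0.02. Angptl4, Ddit4, Cdkn1a (0.50) and Lcn2 (0.46) led, and each of these is also on another list. Camera's adjusted p was 0.00131 and 0.000515, and adjusted p = 0.791 for both with an estimated correlation. Without day 5 the glucocorticoid median was 0.28 (adjusted p = 1.15e-09). Genes of the unfolded protein response did not pass (median -0.00, adjusted p = 0.844), with Hspa5 at 0.07 and Ddit3 at 0.17. In all, 14 of 42 lists passed camera with the preset correlation (11 higher, 3 lower). With estimated correlations camera called 0 of them, with 1 list at an unadjusted p under 0.05, and fry called 0, with 2 lists at an unadjusted p under 0.05.

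The remaining lists did not pass over the 3 days. Their median differences were -0.02 for mature enterocyte and brush border genes (Alpi 0.06), 0.13 for stem cell genes, -0.08 for proliferation, 0.03 for inflammation and antimicrobial genes, 0.10 for cell death, 0.09 for oxidative stress and -0.03 for hypoxia. They were -0.01 for xenobiotic metabolism, -0.10 for retinoid and cholesterol handling, -0.06 for proximal and 0.13 for distal small intestine genes, -0.11 for the circadian clock and 0.02 for male-linked genes. By day the male-linked median was 0.39, -0.25 and 0.08. The mean and the median had opposite signs for brush border genes (mean 0.02), hypoxia (mean 0.03), unfolded protein response (mean 0.00), and mast cells and eosinophils (mean -0.07). Xist, expressed from the inactive X chromosome of females, had intensities of 2433 and 1090 in L/L and KO on day 2, 3126 and 3030 on day 3, and 3052 and 1398 on day 5. Its log2 differences were -1.16, -0.04 and -1.13. A differing share of males and females between the pools was not separated from genotype.

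**Figure D2:**
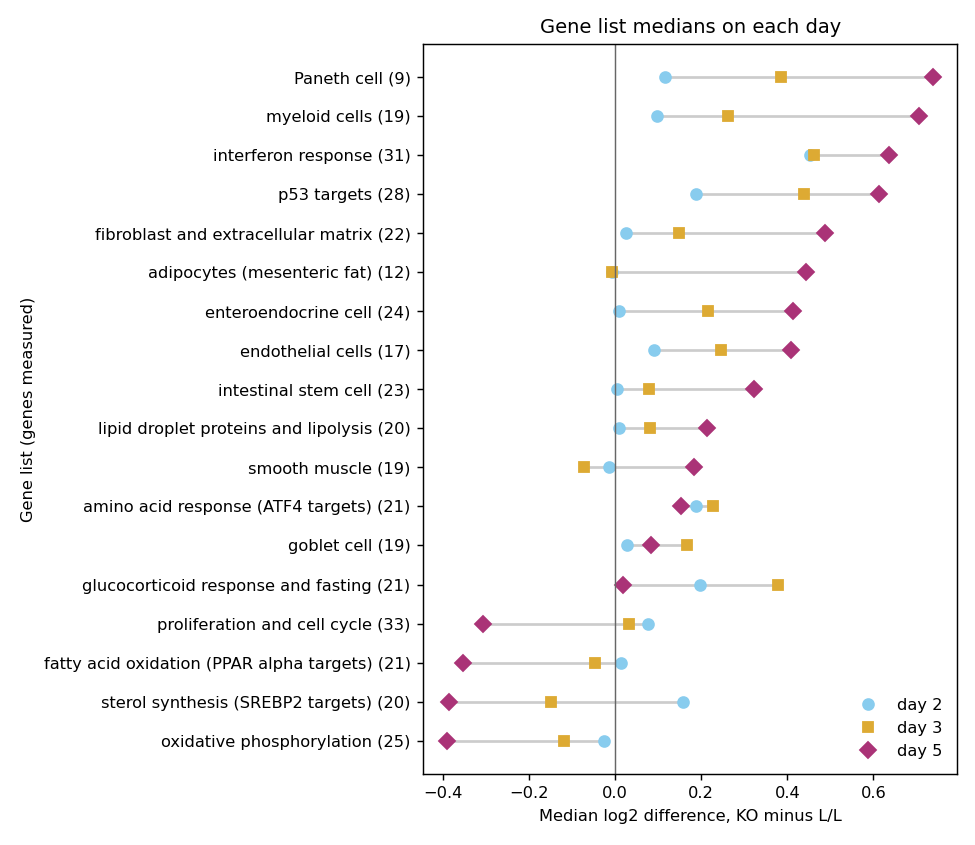
Median log2 difference, KO minus L/L (horizontal), on day 2 (circles), day 3 (squares) and day 5 (diamonds) for the gene lists (vertical, with the number of genes measured) that passed camera with the preset correlation over the 3 days or for the change with day. The interferon list is at 0.45, 0.46 and 0.64, while oxidative phosphorylation goes from -0.03 on day 2 to -0.39 on day 5.

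On day 2 alone, 16 genes differed at least 2-fold between KO and L/L, 12 higher and 4 lower. Highest were Esr1 (log2 2.71), Usp18 (1.59), Glipr1 (1.54), Pla2g4c (1.33), Rgs13 (1.29), Igtp (1.23), Ifit1 (1.22) and Trim30a (1.13). Usp18, Igtp, Ifit1 and Trim30a are induced by interferons. Lowest were Defa31 (-1.87), a Paneth cell defensin, Pla2g2a (-1.30) and Gt(ROSA)26Sor (-1.11), followed by Dio1, Reg3g, Tlr1, Slc40a1 and Mbl2 between -0.89 and -0.70. Rgs13 in L/L (25.5) and Tlr1 in KO (24.2) were below the filter threshold, so their differences are bounded only at 0.67 and -0.08. With 1 array per group a single day has no test. As a background, 26 genes differed at least 2-fold between L/L day 3 and L/L day 2, more than between the genotypes on day 2. Those L/L pools also differed in day, so their count holds any change with day. The median absolute log2 difference was 0.119 for that L/L pair and 0.067 for KO against L/L on day 2. The interferon median on day 2 lay at the 100th percentile of 10000 random lists matched on expression, and at percentile 99.2 for L/L day 5 against L/L day 2 (median 0.13). For L/L day 3 against L/L day 2 the interferon median was larger, at 0.25.

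On day 3, 36 genes differed at least 2-fold, 24 higher and 12 lower. Esr1 (3.05), Psrc1 (2.29), Slc15a2 (1.91), Phlda3 (1.59), Ephx1 (1.57), Pla2g2a (1.53), Glipr1 (1.52) and Cxcl10 (1.35) were highest. Gsdmc2 (-3.40), Pla2g4c (-2.01), Car4 (-1.83), Gt(ROSA)26Sor (-1.77), Pbld1 (-1.36), Nox4 (-1.29), Capn13 (-1.22) and BC064078 (-1.21) were lowest. Slc15a2 in L/L (18.5), Pbld1 in KO (24) and Nox4 in KO (30.6) were below the filter threshold, which bounds their differences at 0.83, -0.66 and -0.94. A second Slc15a2 probe set was at 0.14. Pla2g4c and Pla2g2a had opposite signs on days 2 and 3. Glucocorticoid and fasting genes were at the 100th percentile of matched random lists (median 0.38; Angptl4 1.25, Ddit4 0.94, Pdk4 0.61 and Pck1 0.53), and all 12 pancreatic acinar genes were higher (median 0.40; Ctrb1 0.85 and Ctrl 0.71). In L/L alone the medians of these lists were -0.23 and -0.39 from day 2 to day 3, and -0.25 and -0.30 from day 2 to day 5. The L/L pools of days 3 and 5 were thus both lower than that of day 2.

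On day 5 the genotypes had moved much further apart: 282 genes differed at least 2-fold, 167 higher and 115 lower. Defa31, whose only probe set is of a type that can bind several transcripts, stood out at log2 8.16, with intensities of 10116 in KO and 35.3 in L/L, the latter below the filter threshold of 38.9 and far from the other 4 arrays at 2772 to 10152. Next came Il1rn (3.55), the interleukin-1 receptor antagonist, Esr1 (3.16), Saa3 (3.09), an acute-phase protein, Psrc1 (2.82), the keratin gene Krt23 (2.65), Ly6d (2.42) and Sptssb (2.22), a subunit of serine palmitoyltransferase. Lowest were Gsdmc2, Car4 (-4.22), Dmbt1 (-3.93), Pla2g4c (-3.03), Ugt2b5 (-2.66), Slc1a1 (-2.39), Akr1c14 (-2.12) and Reg3a (-2.03). Gsdmc2 went from 1303 in L/L to 5.66 in KO, below the filter threshold, so its measured -7.85 stands for a difference of at least -5.07 in size. Il1rn in L/L (21.8) was also below it, for a bound of 2.71, and Defa31 and Sptssb have bounds of 8.02 and 2.16. A second Slc1a1 probe set was at -1.39 and a second Pla2g4c probe set at -2.20. Between L/L day 5 and L/L day 2, 54 genes differed at least 2-fold.

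Epithelial markers on day 5 went in several directions. The stem cell marker Olfm4 was lower (-1.97, from 6061 to 1545) and Lgr5 slightly so (-0.35), whereas Sox9 (1.43), Rnf43 (1.23) and Igfbp4 (0.81) were higher, and the stem cell list had a median of 0.32. Proliferation genes had a median of -0.31, with Tk1 (-1.10), Ccnb2 (-1.07), Mki67 (-0.98) and Birc5 (-0.97) lowest. Brush border genes had a median of -0.04 (Ada 1.45, Xpnpep2 -0.98). The antimicrobial list held both Il1rn and Saa3 at the top and Reg3a and Reg1 (-2.01) at the bottom, for a median of 0.18. Of the p53 targets, 9 were at least 2-fold higher and none 2-fold lower. Oxidative phosphorylation genes were lower in all 25 cases, with Ndufs1 (-0.71), Cyc1 (-0.70), Uqcrfs1 (-0.65) and Sdha (-0.54) lowest. Lists at the 100th percentile of matched random lists were Paneth cell, myeloid, interferon, p53, fibroblast, enteroendocrine and adipocyte genes. At the 0th percentile were sterol synthesis, oxidative phosphorylation and proliferation genes. Such percentiles also occurred between the L/L pools of days 5 and 2, at 0 for enteroendocrine, glucocorticoid and inflammation genes and at 100 for sterol synthesis and smooth muscle genes.

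**Figure D3:**
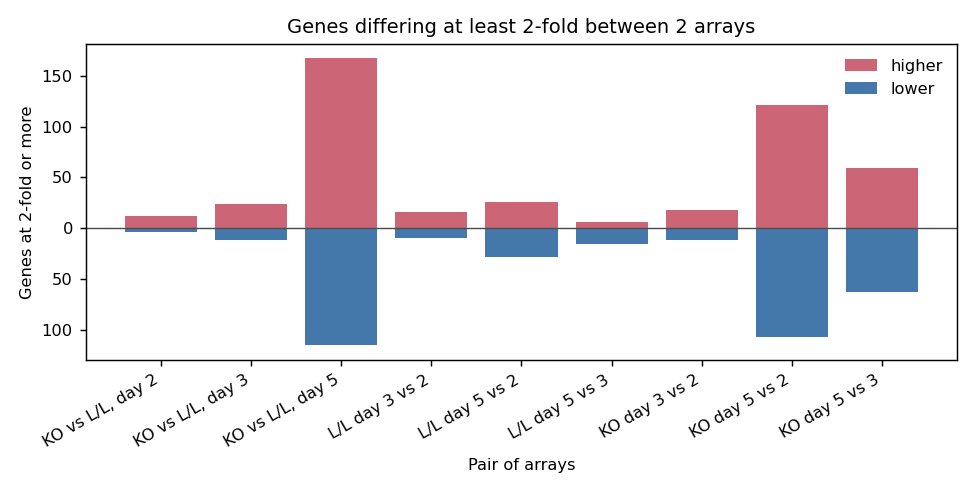
Number of genes differing at least 2-fold (vertical; higher upwards in red, lower downwards in blue) between the arrays of each pair (horizontal), out of 13042. KO against L/L gives 16, 36 and 282 genes on days 2, 3 and 5, while pairs of L/L arrays give 21 to 54.

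Whether the genotype difference itself changed with day was tested as a linear slope from day 2 to day 5. It changed in 160 genes, of which 84 rose and 76 fell in KO relative to L/L. The steepest rises in log2 per day were those of Defa31 (3.42), Il1rn (1.15 ± 0.12 SE, adjusted p = 0.0373), Saa3 (1.08 ± 0.06 SE, adjusted p = 0.00876), Krt23 (1.00), Ly6d (0.78), Sptssb (0.71), Ajuba (0.68) and Anxa8 (0.65). The steepest falls were those of Gsdmc2 (-2.72), Car4 (-1.33 ± 0.07 SE, adjusted p = 0.00876), Dmbt1 (-1.26), Ugt2b5 (-0.90), Akr1c14 (-0.78), Slc1a1 (-0.78), Olfm4 (-0.70) and ccdc198 (-0.66). With intensities below the filter threshold raised to it, the slopes were -1.72 for Gsdmc2, 0.95 for Il1rn and 3.37 for Defa31. For the myeloid gene Cd68 the slope was then 0.24 (0.35 as measured). The value for Il1rn is not a bound, as both of its day 2 intensities were raised. In L/L alone, Defa31 changed by -8.03 from day 2 to day 5 after the same step, so its slope also holds this fall in the controls. Among other genes of the lists, Ccng1 and Zmat3 (p53 targets), Chga, Gip, Chgb and Gcg (enteroendocrine), Sox9 and Rnf43 (stem cell), Lyz2 and Cd68 (myeloid), Ada and Vldlr rose, and Chpt1, which makes phosphatidylcholine, Ccnb2, Birc5, Pdk1, Gstm3 and Ces1f fell. Limma gave 2404 genes at an unadjusted p under 0.05 against 652 expected. The slope rests on 1 residual degree of freedom plus the prior, and its count went from 0 to 549 under other settings. It was 0 without the intensity filter, where limma had 2475 genes at an unadjusted p under 0.05.

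By list, 14 of 42 changed with day in camera with the preset correlation. Of these, 10 rose in KO relative to L/L: myeloid (median slope 0.22 per day), enteroendocrine (0.16), p53 targets (0.16), Paneth cell (0.15), adipocyte (0.14), fibroblast (0.13), smooth muscle (0.10), endothelial (0.09), lipid droplet (0.08) and stem cell genes (0.07). The other 4 fell: sterol synthesis (-0.16), fatty acid oxidation (-0.14), oxidative phosphorylation (-0.13) and proliferation (-0.12). From day 2 to day 5 adipocyte genes had a median of -0.05 in KO and -0.25 in L/L, lipid droplet genes 0.02 and -0.15, enteroendocrine genes 0.08 and -0.39, endothelial genes 0.13 and -0.18, and sterol synthesis genes -0.15 and 0.22, so for these 5 lists the shift in L/L was the larger one. Adjusted p lay between 3.61e-09 for oxidative phosphorylation and 0.0281 for stem cell genes. The stem cell call was lost with the stricter filter (adjusted p = 0.0997). With an estimated correlation camera called 0 of them (smallest adjusted p = 0.747, and 0 lists at an unadjusted p under 0.05). The interferon list did not pass camera with the preset correlation for a change with day (median slope 0.06, adjusted p = 0.521). For brush border genes the median slope was -0.02 and the mean slope 0.01 (adjusted p = 0.909).

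Differences between days within a genotype were read as a background, which holds any change with day as well as differences between pools. In L/L, 26 genes differed at least 2-fold between days 3 and 2, 54 between days 5 and 2, and 21 between days 5 and 3. From day 2 to day 5 in L/L, Pla2g4c (log2 2.75), Gsdmc2 (2.24), Ms4a4b (1.83), Scd2 (1.74) and Sprr1a (1.62) were highest, and Defa31 (-8.17), Pla2g2a (-3.68), Bco1 (-2.77), Akp3 (-2.28) and Hp (-1.91) were lowest. Ms4a4b on L/L day 2 and Defa31 and Akp3 on L/L day 5 were below the filter threshold, which bounds their differences at 1.45, -8.03 and -2.16. Several genes with the largest genotype differences on day 5 therefore also differed between the control pools. Car4, for example, was 1.49 higher in L/L on day 5 than on day 2, and enteroendocrine genes had a median of -0.39 in the same comparison. In KO the counts were 30, 228 and 122 genes for the same pairs of days.

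Across genes, the differences on days 3 and 5 resembled each other most (Pearson r = 0.587, Spearman rho = 0.515), with r = 0.288 for days 2 and 3 and r = 0.264 for days 2 and 5. These differences share no array. The correlations are over 13042 genes, which are not independent replicates.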

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

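A difference between groups, here a genotype difference that changed from day to day by the test of its slope, marked 160 genes. The genes named for it, in log2 per day, were Defa31 (3.42), Il1rn (1.15), Saa3 (1.08), Krt23 (0.997), Ly6d (0.782), Sptssb (0.706), Ajuba (0.676) and Anxa8 (0.649), which rose, and Gsdmc2 (-2.72), Car4 (-1.33), Dmbt1 (-1.26), Ugt2b5 (-0.897), Akr1c14 (-0.782), Slc1a1 (-0.778), Olfm4 (-0.695) and ccdc198 (-0.661), which fell. Defa31 on L/L day 5 (35.3) and Gsdmc2 on KO day 5 (5.66) were below the filter threshold of 38.9. With these raised to it the slopes were 3.37 and -1.72, and Defa31 changed by -8.03 in L/L alone from day 2 to day 5. The only Defa31 probe set is of a type that can bind several transcripts.

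The same test of a difference between days marked 14 gene lists, by median slope: myeloid (0.223), p53 targets (0.157), enteroendocrine (0.157), Paneth cell (0.154), adipocyte (0.139), fibroblast and matrix (0.128), smooth muscle (0.0955), endothelial (0.0946), lipid droplet (0.0771) and stem cell genes (0.0696) upwards, and sterol synthesis (-0.156), fatty acid oxidation (-0.137), oxidative phosphorylation (-0.127) and proliferation (-0.123) downwards. With an estimated correlation camera called 0 of these lists (smallest adjusted p = 0.747, 0 lists at an unadjusted p under 0.05).

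Whether other splits of the 6 arrays into 3 and 3 give as many calls was a test chosen before the results were seen. For genes over the 3 days the real split called 3 and the highest other 93, and 3 of 10 splits, the real one included, called as many. The 93 came from the splits that part only day 5, which points to a structure of the samples, the distance of KO day 5 from L/L day 5. They fit the same contrast of day 5, unlike the real split, which parts every day; of the 4 splits that do so, the other 3 called no gene. For lists the real split called 14, the highest other 15, and 6 of 10 called as many. For slopes, over the splits that part every day, the real split called 160 genes and the highest other 96 (1 of 4 as many), and 14 lists against 16 (3 of 4 as many). There are too few splits for a share under 0.05.

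The tests on p53 targets were chosen only after the result was seen. The list median was 0.411 at its lowest without probe sets that can bind several transcripts or with the stricter filter, against 0.414, so it hardly depended on these settings. Disagreement between probe sets of the same gene was not part of this test. Cre activity with tamoxifen can itself damage DNA, and p53 targets respond to DNA damage. With 0 arrays of tamoxifen-treated Cre mice with intact Fitm2, an effect of Cre and an effect of Fitm2 loss cannot be told apart.

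The tests on interferon genes were also chosen only after the result was seen. On day 2 the highest of 3 immune list medians was 0.0963 against 0.454 for interferon genes. On day 5 myeloid genes reached 0.705 against 0.635, while T and NK cell genes were at -0.157 and B and plasma cell genes at 0.0251. More immune cells in the KO pools are therefore not excluded, with myeloid genes alone near the interferon median. Differences between pools remain open. The same list shifted by up to 0.254 between L/L arrays, below the smallest KO median of 0.454. Gene by gene, the KO difference averaged over days did not exceed the largest absolute L/L shift by more than a permutation of signs gives (mean excess 0.0564, permutation p = 0.18 over 31 genes of the same arrays). This test sets a mean against a maximum, which leans towards no excess, and the L/L shifts also hold any change with day. It therefore cannot decide. An effect of Cre remains open as well, with 0 arrays of Cre mice with intact Fitm2.

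The tests on Esr1 were chosen only after the result was seen. The other Esr1 probe set above the filter differed by 0.104, against 2.97 for the one reported. CreERT2 contains the ligand-binding domain of the estrogen receptor, so a probe set within that domain could detect the transgene, which only KO mice carry. Where each probe set lies was not available. With 0 other Esr1 probe sets above the stricter filter, a rise of the mouse transcript cannot be excluded.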

How the results depend on the processing

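The linear day term, the 1.5-fold minimum and the other codings of the change with day gave counts only. They are left out of the next totals, as are camera with an estimated correlation and fry. Those other codings called 0 slope genes. Across the remaining alternatives, called lists kept direction and side of the threshold in 157 of 168 values over the 3 days and in 111 of 112 for the slope. Called named genes did so in 26 of 36 and 276 of 332. The cause was not tested unless given. Genes called over the 3 days (3) came to 1 with the mean of all probe sets and 6 with a linear day term. Leaving out 1 day, with fewer arrays, gave 0 to 2 genes and 13 to 20 lists. Lists (14) came to 0 with an estimated correlation and 0 with fry. The sterol synthesis median (-0.111) ranged from -0.264 without day 2 to 0.0238, reversed, without day 5.

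Slope genes (160) came to 0 without a filter, 275 with the stricter filter, 549 with the offset of 32 and 512 with the trend and robust settings. They came to 0 in limma with a linear day within each genotype (1311 at an unadjusted p under 0.05) and to 0 for day 5 against days 2 and 3 (2186). Slope lists (14) came to 0 with an estimated correlation.

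For counts at 2-fold, no filter gave 45 for L/L day 3 against 2 and 42 for L/L day 5 against 3, and correlations of 0.178 for days 2 and 3 and 0.465 for days 3 and 5, with more dim genes included. The stricter filter gave 13 for L/L day 5 against 3. The offset, which shrinks differences of dim genes by construction, gave 23 for day 3 and 175 for day 5, then 17, 32 and 8 for L/L and 17, 144 and 70 for KO (day 3 against 2, 5 against 2, 5 against 3). The fit over the 3 days pairs KO with L/L by day; without the day term 3 genes were called, 2 of them shared. Intensities near the threshold of 38.9 limit what dim genes can show.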

Other observations

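Ribosome biogenesis genes were higher in KO from day 2. The list was written after factors of ribosome synthesis had been seen among the smallest p-values, without the genes seen there, and its test was chosen before its own result was seen. Of 41 genes, 38 were higher on all 3 days, with medians of 0.21, 0.20 and 0.33 on days 2, 3 and 5 and 0.245 over the 3 days. Each day's median lay at the 100th percentile of matched random lists. The list was tested on the arrays in which related genes had been seen, so this is not independent support. Its shift between L/L pools was not computed. Utp20 (0.65), Nop16 (0.57), Wdr12 (0.55) and Ddx21 (0.45) had the largest means, genes chosen after their values were seen. No single gene of the list passed over all genes, and camera with an estimated correlation did not call the list.

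Genes described in regenerating epithelium and targets of YAP, several of which are not limited to epithelium, rose in KO with day, with a median slope of 0.222 per day over 21 genes. The median slopes of non-epithelial lists were 0.223 for myeloid, 0.128 for fibroblast, 0.0955 for smooth muscle and 0.0946 for endothelial genes. This list, too, was written after similar genes had been seen among the largest day 5 differences and without those genes, and its test was chosen before its own result was seen. Its medians were 0.05, 0.10 and 0.745 on days 2, 3 and 5, and all 21 genes were higher on day 5. These values come from the arrays in which similar genes had been seen and are not independent support. Tnfrsf12a (0.58 per day), S100a6 (0.52) and Clu (0.35), also chosen after their values were seen, passed the slope test in limma. Camera with an estimated correlation did not call the list.

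Xist had intensities of 2433, 3126 and 3052 in L/L and 1090, 3030 and 1398 in KO on days 2, 3 and 5, and the Y-linked Eif2s3y 338, 326 and 466 in L/L and 497, 273 and 635 in KO.

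Pla2g2a varied between pools of both genotypes, with intensities of 1397, 478 and 109 in L/L and 569, 1382 and 230 in KO. Defa31 stood at 10152, 6213 and 35.3 in L/L and 2772, 8196 and 10116 in KO.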
